A study of Mus musculus with 32 samples.

How the data were processed

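Microglia were sorted by yellow fluorescence from the cortex of C57BL/6 mice at the stab wound or at the matching site of the non-injured hemisphere, per the labels' protocols. Days 1, 4, 7 and 14, both sexes and both sides gave 16 groups with 2 columns each, 32 in all. The cDNA was made with SMART-Seq v4 and the libraries with Nextera XT, a protocol that does not keep the strand. The submitters' processing notes name Salmon 1.0.0 and DESeq2 1.26.0. Genome build, annotation release and settings are not given in the sources used here. The deposited expected counts are estimated reads per gene for 55385 versioned Ensembl gene IDs, not normalized, with the largest values rounded in the file. The authors also deposited TPM values (transcripts per 1e+06), and a table of normalized counts, a signal whose ratio to the counts is nearly constant within a column. The deposited comparison tables hold a log2 fold change, injured over non-injured, per the file headers, with its standard error as a score, a p-value, an adjusted p-value and a mean normalized signal. Symbols came from the GENCODE M21 annotation of GRCm38, in which 54487 of the IDs were found, and coordinates are from that annotation. All 32 count columns were used and 0 were left out.

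The replicate numbers were first checked. For genes with at least 20 counts over both columns of a group, a chi-square with 1 degree of freedom compared the columns, scaled to their totals. Its median was 0.473 to 0.633 over the 16 groups, against 0.455 for counting noise, and the total of 1 column lay between 99.69% and 100.5% of the other except for 96.16% in the day 7 female non-injured group. A fit of 32 separate samples would take counting noise for the spread between animals. The 2 columns of each group were therefore summed and rounded, which departs from the design written before the data were examined, where the 32 columns were separate samples. Deviations of equal replicate numbers on both sides correlated between -0.0408 and 0.0534 across genes. Counting noise gives such values whether or not the numbers pair the samples, so this does not decide it. The pairs used are the injured and non-injured libraries of 1 day and sex, whose labels share no animal identifier. Because the columns were summed, each comparison within 1 sex and day, and the sex difference at a single day, had no residual degrees of freedom and was not tested.

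Counts were tested in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood with TMM factors and the current dispersion estimate. Genes passed filterByExpr at a minimum count of 10 on the groups of day and side, which left 28597, of which 18373 are protein-coding. The model held 8 pair means and 4 day effects of injury, with 4 residual degrees of freedom and 5.32 prior degrees of freedom. It was chosen after several fits had been compared. The mean of the 4 day effects, the sex difference of that mean, and fits of the 4 female or 4 male pairs alone were added after the values had been seen. Non-injured libraries were fitted with day and sex. Standard errors are the log2 change over the square root of F, left empty above 100. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. CPM values use library sizes times TMM factors. The 37 lists (21 gene lists and 16 lists of cell type markers, among 18 marker lists with the 2 for sex) were written before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. List medians of pair log2 ratios (1 CPM added), relative to the median of the 9025 genes at a mean of at least 10 CPM, were tested by exact sign flips of 8 pairs and exact permutation of 4 against 4.

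Named genes followed a rule written before the data were examined. For each day it took up to 8 rises and 8 falls, the largest among called genes at a mean of at least 10 CPM in that day's libraries, with all 4 injured columns beyond all 4 non-injured ones. Predicted gene models were left out. For the remaining planned tests it took up to 10 genes by smallest p at a mean of at least 10 CPM, besides the reporter gene and the sex-linked genes. For the added mean over days and the fits within a sex, genes had to move alike in all pairs. List members were to be the called ones with the largest fold, and others printed for contrast, such as Trem2, Il6 and Gfap, were chosen after their values were seen. Not every gene of the rule is printed, and some results for single genes are withheld for evaluation and not reported here. A fold change of a called gene is given only where most libraries on the lower side held at least 10 counts, a rule chosen after the values were seen, and CPM means are given otherwise. Means without the highest library of a side were also added after the values were seen, and are printed beside most means that 1 library moves by over 1.5 times.

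Alternatives were median-ratio factors, DESeq2 1.42.0, no filter, limma on log2(TPM + 1), a 2-fold threshold, only the libraries compared, leaving out each pair, and the replicate block. Others were added after the data had been seen and are named with their effect. Median-ratio factors shifted the median gene by -0.27 at day 4, -0.37 at day 7 and -0.14 on average. The tests were tested on simulated data with 200 changed genes, a dispersion of 0.2 and 23331 genes run. At simulated log2 changes of 1, 2 and 3, the mean over days recovered 34.3%, 97% and 100% of changed genes with 5 unchanged genes called. Single days recovered 0%, 5.97% and 63.6% at day 1, 0%, 13.4% and 74.2% at day 4, 1.49%, 2.99% and 57.6% at day 7, and 1.49%, 5.97% and 53% at day 14. In the same data the camera p-value was 1.6e-108 for 25 raised genes and 0.69 for 25 unchanged ones. Simulated genes were drawn independently, with the same effect in all days and both sexes. The simulation therefore cannot decide between a preset and an estimated correlation, and its recovery rates hold for such equal effects only. Depth was 20863982 to 55378788 counts per summed library.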

Results

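The series measured polyadenylated RNA of fluorescent microglia sorted from mouse cortex 1, 4, 7 and 14 days after a stab wound. The mice were heterozygous for a tamoxifen-inducible recombinase in the fractalkine receptor gene Cx3cr1, which switches on a yellow fluorescent protein in microglia. Cells came from the wound site or from the matching site of the non-injured hemisphere, in females and in males. The 16 combinations of day, sex and side were each deposited as 2 columns. The series description calls these biological replicates, yet the 2 columns of a combination differed by little more than counting noise. Their median chi-square per gene ran from 0.473 to 0.633, where counting noise alone gives 0.455. Between the sexes at the same day and side it ran from 19.8 to 72.4. The columns were therefore summed into 16 libraries, which form 8 day-by-sex pairs of an injured and a non-injured library. The labels do not say which samples come from separate animals, so every p-value measures only the spread between these samples. Each day, sex and side had 1 library, so no spread between replicates was estimated. In the main fit the spread is the difference between the female and male injury effects within a day. In the fits of 1 sex alone it is the variation of the injury effect between days.

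Summed libraries held 20863982 to 55378788 counts and detected 14737 to 40975 genes. The sex labels matched in 16 of 16 libraries for each of the 6 sex-linked genes examined. Xist, the non-coding RNA that silences an X chromosome, lay between 97.1 and 302 CPM (counts scaled to a common library size) in female libraries and at most at 2.7 CPM in male ones. Ddx3y, a Y-linked helicase gene, lay at 0 in females and between 41 and 145 CPM in males. The reporter gene Cx3cr1 averaged 46.45 CPM on the injured side and 49.37 CPM on the other, and 21.8 CPM on the injured side without the day 4 female library (219 CPM). It was lower at the wound in 7 of 8 pairs (exact two-sided sign-flip p = 0.0312, adjusted over 21 measures 0.0655), and its fitted difference was not called (log2 -0.65, SE 0.23, adjusted p = 0.0901). Mitochondrial transcripts averaged 2.758% of counts on the injured side against 6.38% (3.62% without the day 4 male non-injured library, at 25.7%), and were lower in 7 of 8 pairs (exact two-sided sign-flip p = 0.0391, adjusted over 21 measures 0.0746, 8 pairs).

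The first comparison asked how microglia at the wound differ from those of the non-injured hemisphere, averaged over the 4 days. Microglia at the wound carried less of the surveillance receptor set of resting cells and more of the genes of phagocytic, lipid-loaded cells. Lists of genes for matrix breakdown, iron handling, interferon response, DNA replication, ribosomes and monocytes were higher as well, and those of neurons and blood vessels were lower. These are camera calls at a preset correlation, and 0 of 37 lists were called with an estimated correlation (smallest adjusted p = 0.065). In edgeR, 4496 of 28597 genes were called (adjusted p under 0.05), of which 2219 rose, 2277 fell and 3609 changed at least 2-fold. Of those that rose, 1263 were higher in all 8 pairs, and of those that fell, 992 were lower in all 8. Chance gives 0.391% in a given direction for unselected genes, and these genes were first called on the same pairs. The average over days was chosen as a comparison after the values had been seen. The count fell to 1758 without the day 1 female pair, 2099 without the day 1 male pair, 2577 without the day 7 female pair and 2215 without the day 7 male pair. The share of calls that rose was 25% in limma on log2 TPM (1092 higher, 3279 lower), 40.7% with median-ratio scaling and 74.3% without the day 4, 7 and 14 male pairs (3268 higher, 1130 lower).

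The largest rise at a mean of at least 10 CPM was that of Spp1, which encodes the secreted phosphoprotein osteopontin. It rose by 7.70 on the log2 scale (SE 0.61, adjusted p = 0.000177), from 324.2 CPM (86.57 CPM without the day 7 male library) to 31390 CPM, and was higher in 8 of 8 pairs. Gpnmb, a lysosome-linked membrane glycoprotein gene, rose by 6.42 (SE 0.81, adjusted p = 0.00129), and Lgals3, the galectin-3 gene, by 6.28 (SE 0.57, adjusted p = 0.000327). Htr2b, a serotonin receptor gene, averaged 35.67 CPM at the wound against 3.302 CPM (0.257 without the day 7 male library), and Ly6c2, a surface antigen gene of blood monocytes, 25.55 CPM against 0.9592 CPM (0.3779 without it). Apoc2, which encodes the activator of lipoprotein lipase, averaged 102.8 CPM against 3.497 CPM (64.44 and 0.5444 without the day 7 male pair), and Slfn1, a schlafen family gene of the interferon response, 27.89 CPM against 2.027 CPM (0.1872 without that library). Igkc, the immunoglobulin kappa constant region of antibody-making cells, averaged 61.21 CPM against 5.565 CPM (0.07037 without that library, at 44.02 CPM). These 5 genes were called. Among falls, Gpr165, an orphan receptor gene on the X chromosome, averaged 0.6231 CPM at the wound against 20.08 CPM (0.1395 against 7.027 without the day 4 female pair, adjusted p = 0.000208). Upk1b, a tetraspanin gene known from urothelium, fell by 4.65 (SE 0.26, adjusted p = 7.36e-05), from 159.2 to 6.739 CPM (101.4 to 4.052 without the day 14 female pair), in 8 of 8 pairs. In the GRCm38 annotation, Spp1 lies on chromosome 5 from 104435118 to 104441050, and Upk1b on chromosome 16 from 38773184 to 38800328.

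Genes of resting microglia were lower at the wound. Of 26 homeostatic microglia genes, 18 fell, 1 rose and 7 were not called, and adjusted over the list alone 20 fell and 1 rose (median log2 -1.09, camera adjusted p = 1.7e-12, and 0.16 with an estimated correlation). Slc2a5, the fructose transporter gene, fell by 2.94 (SE 0.19, adjusted p = 8.8e-05). P2ry12, the receptor by which processes sense ADP, fell by 2.50 (SE 0.22, adjusted p = 0.000275), from 4322 to 810.9 CPM. Selplg, a selectin ligand gene, fell by 2.22 and Tmem119, a membrane protein gene used to mark microglia, by 1.71. Sall1, the transcription factor gene that keeps microglial identity, fell by 1.72, and Csf1r, the survival receptor gene, by 0.86. Fcrls, an Fc receptor-like gene, rose by 0.75. Beside these falls, 15 monocyte markers summed to 750.6 CPM at the wound against 145.8 CPM (higher in 8 of 8 pairs, exact two-sided sign-flip p = 0.00781, adjusted p = 0.041).

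Genes of phagocytic and lipid-loaded microglia were higher. Of 30 disease-associated microglia genes, 27 rose, 0 fell and 3 were not called, and adjusted over the list alone 28 rose (median log2 2.39, camera adjusted p = 6e-27, and 0.12 with an estimated correlation). Lpl, the lipoprotein lipase gene, rose by 4.49 (SE 0.27, adjusted p = 8.8e-05). Clec7a, a receptor gene for fungal glucan, rose by 4.15, and Igf1, an insulin-like growth factor gene, by 3.68. Apoe, the lipid carrier gene, rose by 2.60, from 4132 to 52650 CPM, in 6 of 8 pairs, and its partner receptor gene Trem2 was not called (log2 0.37, adjusted p = 0.224). Of 20 genes for lipid efflux and storage, 13 rose and 7 were not called, and adjusted over the list alone 15 rose and 1 fell (median log2 2.40, camera adjusted p = 1.8e-11, and 0.14 with an estimated correlation). Plin2, a coat protein gene of lipid droplets, rose by 4.06, and Ch25h, a cholesterol hydroxylase gene, by 5.78. Of 32 lysosome genes, 24 rose and 8 were not called, and adjusted over the list alone 26 rose (median log2 1.13, camera adjusted p = 3.2e-17, and 0.16 with an estimated correlation). Ctsb, the cathepsin B protease gene, rose by 2.48, from 3709 to 20830 CPM, and Cd63, a tetraspanin gene of late endosomes, by 2.72.

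Averaged over the 4 days, cholesterol synthesis was not called as a group. Its pair medians lay at 0.45 and 0.35 at day 1 and between -1.59 and -0.01 on the later days, so the average hides opposite directions. Of 24 cholesterol biosynthesis genes, 1 rose, 1 fell and 22 were not called, and 0 were called adjusted over the list alone in edgeR (median log2 -0.26, camera adjusted p = 0.88, and 0.98 with an estimated correlation). Ebp, a sterol isomerase gene, rose by 0.67. Receptors for debris were higher by camera at the preset correlation. By list medians over pairs they were not called (exact two-sided sign-flip, adjusted p = 0.0689, above 0 in 6 of 8 pairs). Of 22 phagocytic receptor genes, 11 rose, 1 fell and 10 were not called, and adjusted over the list alone 12 rose and 2 fell (median log2 0.83, camera adjusted p = 7.5e-07, and 0.16 with an estimated correlation). Msr1, a scavenger receptor gene, rose by 4.88, and Marco, a related collagenous receptor gene, was called, at 200.3 and 142.4 CPM in the day 1 female and male injured libraries. In the day 7 male pair Marco lay at 27.8 CPM at the wound against 39.45 CPM. Of 14 complement genes, 9 rose and 5 were not called, and adjusted over the list alone 11 rose and 1 fell (median log2 1.12, camera adjusted p = 7e-07, and 0.16 with an estimated correlation). C3, the central complement component gene, rose by 4.34, and C1qa, a gene of the initiating complex, by 0.79.

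Immune signalling genes were higher at the wound. Of 36 type I interferon response genes, 30 rose and 6 were not called, and adjusted over the list alone 33 rose (median log2 1.73, camera adjusted p = 4.2e-23, and 0.16 with an estimated correlation). Oas3, an antiviral synthetase gene, rose by 3.58, Zbp1, a nucleic acid sensor gene, by 2.96, and Irf7, a transcription factor gene of the response, by 2.59. Of 31 genes for inflammatory cytokines and NF-kB targets, 22 rose and 9 were not called, and adjusted over the list alone 24 rose (median log2 1.60, camera adjusted p = 1.2e-14, and 0.14 with an estimated correlation). Il1rn, which encodes the interleukin 1 receptor antagonist, rose by 5.98 (SE 0.34, adjusted p = 7.36e-05), while Il1b, interleukin 1 beta itself, rose by 3.30. Il6, the interleukin 6 gene, was not called (log2 -0.50, adjusted p = 0.458). Antigen presentation genes were split. Of 16 MHC class I genes, 12 rose and 4 were not called, and adjusted over the list alone 15 rose (median log2 1.02, camera adjusted p = 1.8e-10, and 0.16 with an estimated correlation). Of 10 MHC class II genes, 5 rose, 2 fell and 3 were not called, and adjusted over the list alone 5 rose and 3 fell (median log2 1.10, camera adjusted p = 0.062, and 0.58 with an estimated correlation). H2-Aa, a class II chain gene, rose by 2.98 and Cd74, the invariant chain gene, by 2.60, while H2-Oa, a gene for a chain that restrains peptide loading, fell by 1.33.

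Genes of the cell cycle and of biosynthesis were higher. Of 31 DNA replication genes, 21 rose and 10 were not called, and adjusted over the list alone 27 rose (median log2 1.45, camera adjusted p = 1.2e-14, and 0.16 with an estimated correlation). Mcm6, a replicative helicase gene, rose by 1.98 and Pcna, the sliding clamp gene, by 1.54. Of 32 mitosis genes, 13 rose and 19 were not called, and adjusted over the list alone 20 rose (median log2 1.30, camera adjusted p = 3.6e-09, and 0.26 with an estimated correlation). Cdk1, the mitotic kinase gene, rose by 2.26 and Mki67, a proliferation antigen gene, by 1.62. Of 73 ribosomal protein genes, 68 rose and 5 were not called, and adjusted over the list alone 70 rose (median log2 1.26, camera adjusted p = 7.5e-37, and 0.16 with an estimated correlation). Rpl19, a large-subunit gene, rose by 1.60, from 106.8 to 312.7 CPM. Of 20 glycolysis gene entries, 11 rose and 9 were not called, and adjusted over the list alone 12 rose (median log2 0.93, camera adjusted p = 1.1e-06, and 0.16 with an estimated correlation). Pkm, the pyruvate kinase gene, rose by 2.05. Of 39 respiratory chain genes, 11 rose and 28 were not called, and adjusted over the list alone 18 rose (median log2 0.71, camera adjusted p = 8.7e-11, and 0.39 with an estimated correlation). By list medians over pairs the respiratory chain was not called (exact two-sided sign-flip, adjusted p = 0.12, above 0 in 6 of 8 pairs). Ndufa1, a gene of complex I, rose by 1.38.

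Matrix and iron genes were higher. Of 29 genes for matrix remodelling and adhesion, 26 rose and 3 were not called, and adjusted over the list alone 26 rose (median log2 3.87, camera adjusted p = 2.5e-23, and 0.074 with an estimated correlation). Adam8, a membrane metalloprotease gene, rose by 5.89 and Thbs1, the thrombospondin 1 gene, by 4.48. Of 23 genes for iron, heme and antioxidant defence, 15 rose and 8 were not called, and adjusted over the list alone 16 rose (median log2 1.54, camera adjusted p = 5.6e-12, and 0.14 with an estimated correlation). Hmox1, the heme oxygenase gene, rose by 4.09 (adjusted p = 7.13e-05) and Ftl1, the ferritin light chain gene, by 2.77, from 3261 to 22350 CPM. Of 14 genes of IL-4 and repair-type activation, 7 rose, 2 fell and 5 were not called, and 7 rose and 2 fell adjusted over the list alone (median log2 0.96, camera adjusted p = 0.0046, and 0.16 with an estimated correlation). Arg1, the arginase gene, rose by 5.12, and Chil3, a chitinase-like gene, was called at 26.03 CPM against 0.6703 CPM (0.2591 without the day 7 male library). Of 28 orthologues of neurodegeneration risk genes, 8 rose, 4 fell and 16 were not called, and adjusted over the list alone 9 rose and 5 fell (median log2 0.10, camera adjusted p = 0.15, and 0.59 with an estimated correlation). Ms4a6d, a tetraspan receptor gene, rose by 2.31. Of 21 immediate early and dissociation response genes, 1 rose, 3 fell and 17 were not called, and adjusted over the list alone 3 rose and 5 fell (camera adjusted p = 0.97, and 0.99 with an estimated correlation), and the median (-0.29) and mean (-0.15) log2 lay below 0 while camera ranked the list up. Jun, an immediate early gene, fell by 1.13 and Rgs1, a signalling regulator gene, rose by 1.59.

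**Figure D1:**
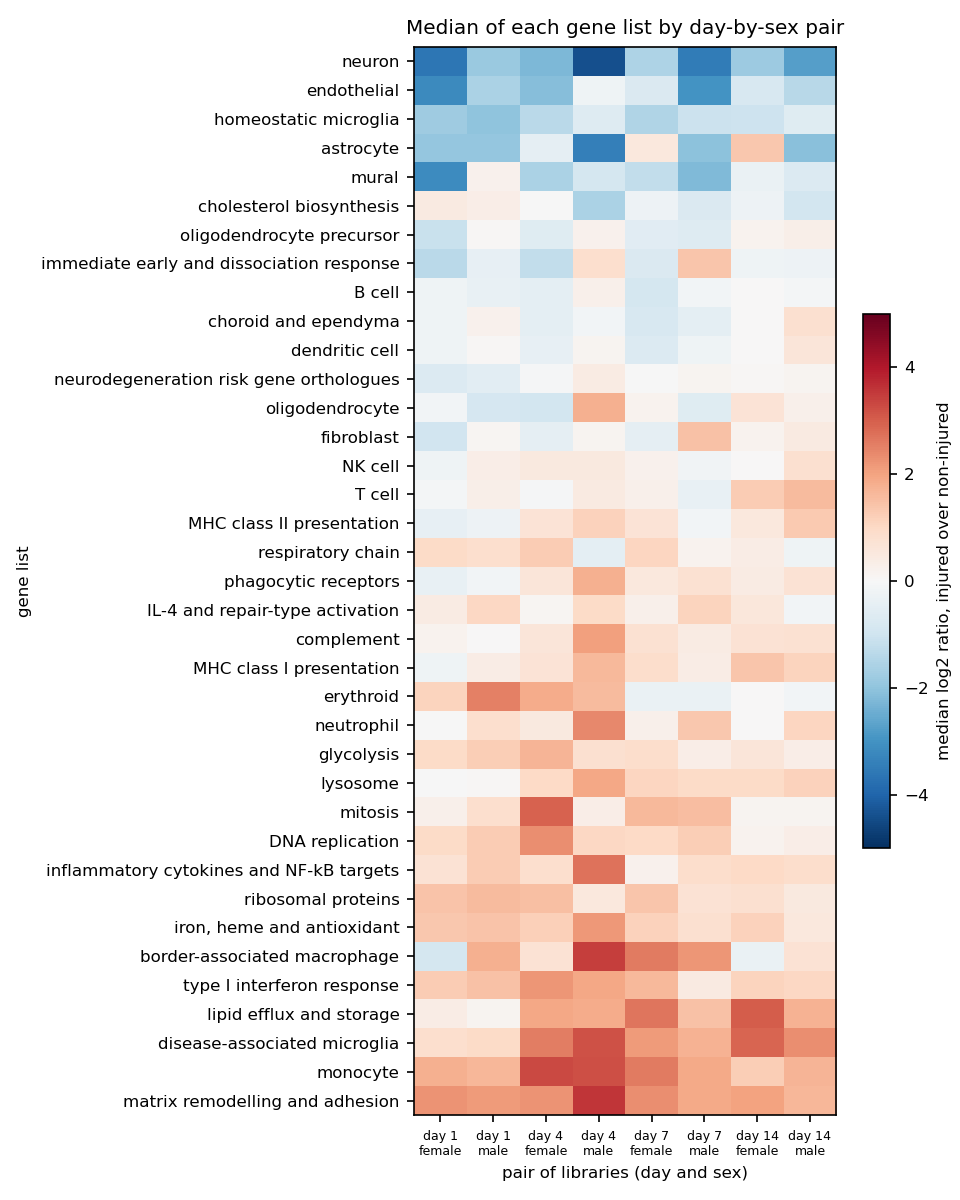
Each cell is the median log2 ratio, injured over non-injured, of a gene list (vertical axis) in a day-by-sex pair (horizontal axis), relative to the median gene at a mean of at least 10 CPM. Neuron markers and homeostatic microglia genes lay below 0 in all 8 pairs, and the lists for disease-associated microglia, matrix remodelling and monocytes lay above 0 in all 8.

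Monocyte markers were higher at the wound in 8 of 8 pairs, and camera also called the border-associated macrophage, neutrophil, T cell and NK cell lists. By list medians over pairs these other lists were not called (exact two-sided sign-flip, adjusted p = 0.101, 0.0577, 0.18 and 0.149, above 0 in 6, 6, 5 and 5 of 8 pairs). Of 15 monocyte markers, 13 rose and 2 were not called, and adjusted over the list alone 14 rose (median log2 3.46, camera adjusted p = 1.4e-11, and 0.065 with an estimated correlation). Ccr2, the chemokine receptor gene of recruited monocytes, rose by 2.81, from 7.008 to 46 CPM. Of 13 border-associated macrophage markers, 6 rose, 2 fell and 5 were not called, and adjusted over the list alone 7 rose and 2 fell (median log2 1.71, camera adjusted p = 0.00096, and 0.39 with an estimated correlation). Ms4a7, a tetraspan gene of such macrophages, rose by 3.77. Of 13 neutrophil markers, 8 rose and 5 were not called, and adjusted over the list alone 9 rose (median log2 4.28, camera adjusted p = 2.8e-05, and 0.16 with an estimated correlation). S100a8, a calcium-binding alarm protein gene, rose by 5.28, while the summed neutrophil markers lay at 362.4 CPM against 309.6 CPM and were higher in 5 of 8 pairs (exact two-sided sign-flip p = 0.445, adjusted p = 0.519). Of 13 T cell markers, 3 rose and 10 were not called, and adjusted over the list alone 8 rose (median log2 1.82, camera adjusted p = 6.7e-07, and 0.12 with an estimated correlation). Of 9 NK cell markers, 3 rose and 6 were not called, and adjusted over the list alone 4 rose (median log2 2.15, camera adjusted p = 0.0031, and 0.16 with an estimated correlation). Of 9 dendritic cell markers, 2 rose and 7 were not called, and adjusted over the list alone 2 rose (median log2 0.55, camera adjusted p = 0.39, and 0.51 with an estimated correlation). Of 8 B cell markers, 1 rose, 2 fell and 5 were not called, and adjusted over the list alone 2 rose and 2 fell (median log2 0.15, camera adjusted p = 0.71, and 0.77 with an estimated correlation). Summed B cell markers lay at 243.2 CPM at the wound against 385 CPM and were lower in 7 of 8 pairs (exact two-sided sign-flip p = 0.0312, adjusted p = 0.0655). Most of the non-injured sum was 1 immunoglobulin gene, Ighm, with 562.3 of 614 CPM in the day 1 female library. In the day 14 male library it made up 181.8 of 197.1 CPM. The sum therefore does not stand for the B cell markers as a group. Of 5 erythroid markers, 1 rose and 4 were not called, and adjusted over the list alone 1 rose (median log2 1.36, camera adjusted p = 0.3, and 0.59 with an estimated correlation).

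Markers of neurons were lower at the wound, and so were the list medians of endothelial markers. Of 14 neuron markers, 13 fell and 1 was not called, and adjusted over the list alone 14 fell (median log2 -3.37, camera adjusted p = 1.4e-11, and 0.16 with an estimated correlation). Slc17a7, the vesicular glutamate transporter gene, fell by 3.99 (SE 0.31, adjusted p = 8.8e-05), and Snhg11, a small nucleolar RNA host gene active in neurons, fell by 4.04. The neuron markers summed to 135.1 CPM at the wound against 2000 CPM, or 856.2 CPM without the day 4 male library at 10010 CPM (lower in 8 of 8 pairs, exact two-sided sign-flip p = 0.00781, adjusted p = 0.041). Other genes with large falls, such as Lingo1, Add2, Lamp5 and Rasd2, are also known from neurons. Of 11 endothelial markers, 7 fell and 4 were not called, and adjusted over the list alone 8 fell (median log2 -1.71, camera adjusted p = 0.00017, and 0.31 with an estimated correlation). Cldn5, a tight junction gene of vessels, fell by 1.64. Endothelial list medians lay below 0 in 8 of 8 pairs (exact two-sided sign-flip p = 0.00781, adjusted p = 0.0193), while the summed markers lay at 945.7 CPM against 1238 CPM and were higher at the wound in 3 of 8 pairs (exact p = 0.336, adjusted p = 0.441). Of 8 mural cell markers, 4 fell and 4 were not called, and adjusted over the list alone 5 fell (median log2 -1.71, camera adjusted p = 0.041, and 0.31 with an estimated correlation). Of 13 astrocyte markers, 2 fell and 11 were not called, and adjusted over the list alone 1 rose and 6 fell (median log2 -1.34, camera adjusted p = 0.049, and 0.64 with an estimated correlation). Slc1a3, a glutamate uptake gene, fell by 1.74, while Gfap, a filament gene of reactive astrocytes, was higher in 8 of 8 pairs and not called (log2 2.99, adjusted p = 0.0528).

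Markers of other resident cells moved little as groups. Of 13 oligodendrocyte markers, 2 fell and 11 were not called, and adjusted over the list alone 1 rose and 2 fell (median log2 0.25, camera adjusted p = 0.56, and 0.83 with an estimated correlation). Mbp, the myelin basic protein gene, fell by 1.12. Of 8 oligodendrocyte precursor markers, 1 rose, 1 fell and 6 were not called, and 1 rose and 1 fell adjusted over the list alone (median log2 -0.12, camera adjusted p = 0.84, and 0.93 with an estimated correlation). For 8 fibroblast markers, edgeR called 0, and 0 adjusted over the list alone (median log2 0.52, camera adjusted p = 0.59, and 0.64 with an estimated correlation). For 6 choroid and ependyma markers it called 0, and 0 adjusted over the list alone (median log2 0.15, camera adjusted p = 0.52, and 0.6 with an estimated correlation). Over 37 lists, camera called 26 (21 up and 5 down), and 0 with an estimated correlation, where the smallest adjusted p was 0.065. An exact two-sided sign-flip test of list medians over 8 pairs called 19 of 37 (smallest p possible 0.00781, adjusted 0.0193).

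**Figure D2:**
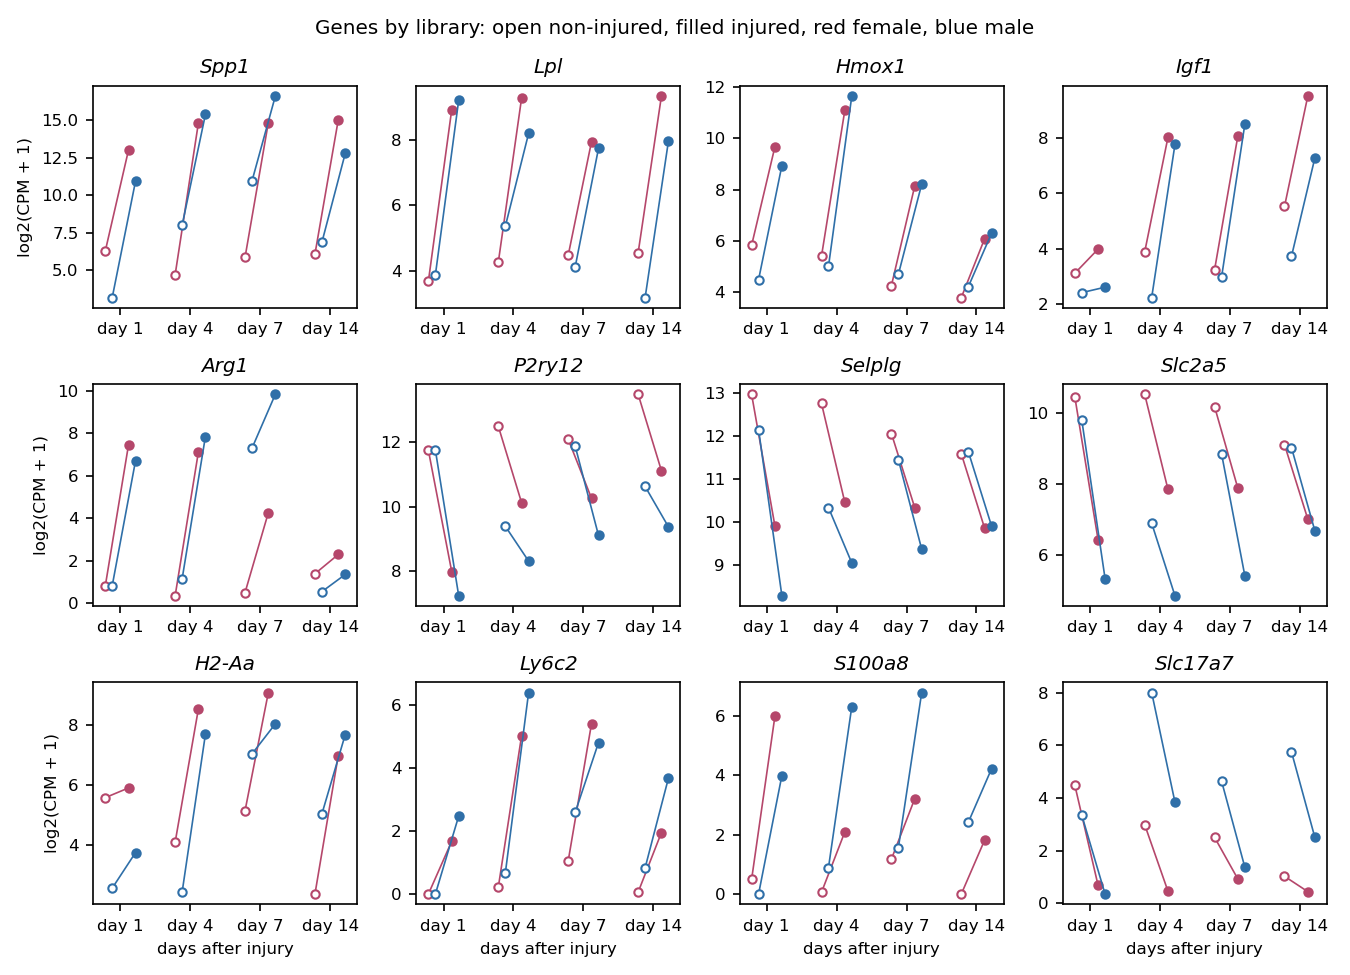
Each panel shows log2(CPM + 1) of a gene (vertical axis) by day after injury (horizontal axis). Open points are non-injured and filled points injured libraries, red for females and blue for males, and lines join the 8 pairs. Spp1, Lpl and Hmox1 were higher at the wound in 8 of 8 pairs, and P2ry12, Selplg and Slc2a5 lower in 8 of 8.

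At day 1 homeostatic genes had their lowest list median of the 4 days, beside higher monocyte markers. In edgeR, 301 genes were called, 135 higher and 166 lower (44.9% higher, against 59.7% without the day 4, 7 and 14 male pairs and 35.4% in limma on log2 TPM). Of 26 homeostatic genes, 13 fell and 13 were not called, and adjusted over the list alone 22 fell (median log2 -1.89, camera adjusted p = 6.7e-19, and 0.33 with an estimated correlation). Slc2a5 fell by 4.27 (adjusted p = 0.00609), P2ry12 by 4.15, Siglech, a sialic acid receptor gene, by 3.79, Selplg by 3.46 and Tmem119 by 2.74. Upk1b fell by 5.68, and Nrsn1, a neurosecretory vesicle gene, by 5.18. Dlgap3, a synaptic scaffold gene, fell by 5.76, Shank1, another such scaffold gene, by 4.91, and Itm2a, a membrane protein gene of vessels, by 4.76. Nefl, a neurofilament gene, averaged 1.015 CPM at the wound against 33.65 CPM, Spock2, a brain proteoglycan gene, 1.367 CPM against 38.04 CPM, and Car4, a carbonic anhydrase gene, 0.9742 CPM against 30.8 CPM, and these 3 genes were called as well. Of 14 neuron markers, 5 fell and 9 were not called, and adjusted over the list alone 14 fell (median log2 -3.95, camera adjusted p = 1.3e-09, and 0.33 with an estimated correlation). Of 11 endothelial markers, 1 fell and 10 were not called, and adjusted over the list alone 7 fell (median log2 -3.01, camera adjusted p = 0.00053, and 0.49 with an estimated correlation). Of 15 monocyte markers, 4 rose and 11 were not called, and adjusted over the list alone 8 rose (median log2 2.35, camera adjusted p = 6.3e-09, and 0.33 with an estimated correlation). Of 13 neutrophil markers, 3 rose and 10 were not called, and adjusted over the list alone 6 rose and 1 fell (median log2 4.73, camera adjusted p = 0.00014, and 0.33 with an estimated correlation). The summed neutrophil markers went the other way, at 268.4 CPM against 431.8 CPM in the female and 134.5 CPM against 436.7 CPM in the male pair, and this difference was not tested.

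Among day 1 rises, Adam8 rose by 7.57 (SE 0.74, adjusted p = 0.00677), from 7.425 to 1362 CPM. Arg1 rose by 7.51, Ch25h by 7.38 and Mmp12, the macrophage elastase gene, by 7.94. Acod1, the itaconate-making enzyme gene, averaged 62.61 CPM at the wound against 0.109 CPM, and Fosl1, an AP-1 subunit gene, 22.46 CPM against 0.05449 CPM. S100a8 averaged 38.42 CPM against 0.202 CPM and Htr2b 26.84 CPM against 0.1622 CPM. These 4 genes were called too, with too few counts on the non-injured side for a fold. Il1rn rose by 7.34 and Hmox1 by 4.17. Of 29 matrix genes, 9 rose and 20 were not called, and adjusted over the list alone 22 rose (median log2 3.17, camera adjusted p = 2.6e-14, and 0.33 with an estimated correlation). Of 30 disease-associated genes, 7 rose and 23 were not called, and adjusted over the list alone 12 rose and 1 fell (median log2 1.14, camera adjusted p = 7.7e-07, and 0.36 with an estimated correlation). Of 20 glycolysis gene entries, 2 rose and 18 were not called, and adjusted over the list alone 10 rose and 1 fell (median log2 1.17, camera adjusted p = 0.00014, and 0.36 with an estimated correlation). Of 22 phagocytic receptor genes, 3 rose and 19 were not called, and adjusted over the list alone 5 rose and 4 fell (median log2 -0.37, mean 0.69, camera adjusted p = 0.6, and 0.84 with an estimated correlation). Igf1 (log2 0.62) and Apoe (log2 -1.55) were not called at day 1. Of 73 ribosomal protein genes, edgeR called 0, against 61 higher adjusted over the list alone (median log2 1.57, camera adjusted p = 4.7e-32, and 0.36 with an estimated correlation). At 2 pairs per day, simulated genes with a 2-unit log2 change were recovered in 5.97% of cases at day 1. The count of calls ran from 0 without a day 1 pair to 845 without the day 4 female pair.

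At day 4 genes of disease-associated, interferon-responding and antigen-presenting microglia were higher, as were replication genes and monocyte markers. In edgeR, 584 genes were called, 435 higher and 149 lower. Without the day 4 male pair 36 were called, 35 higher and 1 lower, and the authors' table lists 1343 higher and 2359 lower. Median-ratio scaling called 626, of which 57% were higher against 74.5%, and shifted the median gene by -0.27. Spp1 rose by 8.77 (SE 1.26, adjusted p = 0.0186), from 140.3 to 35950 CPM. Cd5l, a lipid-binding survival factor gene of macrophages, rose by 8.23 (SE 0.77, adjusted p = 0.00613). Gpnmb rose by 8.34, Arg1 by 8.17, Hmox1 by 6.18 and Igf1 by 4.94. Apoc2 averaged 118.4 CPM at the wound against 0.2597 CPM, and F7, the coagulation factor VII gene, 21.73 CPM against 0.02963 CPM. Gdf3, a growth factor gene of the TGF-beta family, averaged 24.36 CPM against 0.07975 CPM, and Trem1, an activating receptor gene of myeloid cells, 24.48 CPM against 0.1002 CPM. Of 30 disease-associated genes, 21 rose and 9 were not called, and adjusted over the list alone 28 rose (median log2 3.02, camera adjusted p = 1.3e-22, and 0.15 with an estimated correlation). Of 36 interferon genes, 15 rose and 21 were not called, and adjusted over the list alone 28 rose (median log2 2.35, camera adjusted p = 6.3e-21, and 0.16 with an estimated correlation). Rsad2, an antiviral radical enzyme gene, rose by 4.22 and Cxcl10, a T cell attractant gene, by 4.11.

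Of 10 MHC class II genes at day 4, 4 rose and 6 were not called, and adjusted over the list alone 4 rose (median log2 1.47, camera adjusted p = 0.0016, and 0.32 with an estimated correlation). H2-Aa rose by 4.99, H2-Eb1 by 4.84 and Cd74 by 4.30. Of 31 DNA replication genes, 6 rose and 25 were not called, and adjusted over the list alone 24 rose (median log2 2.25, camera adjusted p = 8.2e-16, and 0.15 with an estimated correlation). Of 15 monocyte markers, 9 rose and 6 were not called, and adjusted over the list alone 13 rose (median log2 4.62, camera adjusted p = 1.3e-11, and 0.15 with an estimated correlation). Ccr2 rose by 4.16. Of 14 neuron markers, 4 fell and 10 were not called, and adjusted over the list alone 13 fell (median log2 -4.09, camera adjusted p = 3.9e-08, and 0.18 with an estimated correlation). The day 4 male non-injured library held 10010 CPM of these markers and 25.7% mitochondrial counts, against 277.8 CPM and 1.16% in the female one. Grin1, an NMDA receptor gene, fell by 5.04, with 121.8 CPM in the male and 6.986 CPM in the female non-injured library. Chrm1, a muscarinic receptor gene, was called at 1.199 CPM at the wound against 44.78 CPM (85.72 in the male, 3.831 in the female library), and Grm2, a metabotropic glutamate receptor gene, at 0.8549 CPM against 26.25 CPM. Lamp5, a vesicle protein gene, fell by 4.73, Pcsk2, a prohormone convertase gene, by 4.68, and Syt1, the synaptotagmin gene, by 4.62 (331.9 CPM in the male and 14.01 CPM in the female non-injured library). Upk1b fell by 4.68 and Tmem130, a membrane protein gene, by 4.50. Of 26 homeostatic genes, 5 fell, 1 rose and 20 were not called, and adjusted over the list alone 10 fell and 1 rose (median log2 -0.83, camera adjusted p = 0.00032, and 0.44 with an estimated correlation). Fcrls rose by 1.70. The count of calls ran from 0 without a day 1 pair to 764 without the day 14 female pair.

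At day 7 disease-associated and lysosome genes were higher, and so were the list medians of mitosis genes and monocyte markers. In edgeR, 107 genes were called, 91 higher and 16 lower. This direction turned in DESeq2 (825 higher, 1363 lower) and in limma on log2 TPM (41 higher, 138 lower), and the authors' table lists 1090 higher and 3566 lower. Median-ratio scaling called 91, of which 56% were higher against 85%, and shifted the median gene by -0.37. Spp1 rose by 7.31 (SE 1.21, adjusted p = 0.0477), from 1022 to 64390 CPM. Gdf3 rose by 6.92 (SE 0.78, adjusted p = 0.0213), Cd5l by 5.86, Igf1 by 5.34 and Mmp8, a neutrophil-type collagenase gene, by 5.79. Runx3, a transcription factor gene, rose by 5.01. Mcoln3, a lysosomal channel gene, was called at 65.69 CPM at the wound against 1.927 CPM, Slpi, a protease inhibitor gene, at 61.13 CPM against 1.708 CPM, and Pcsk2 at 0.8468 CPM against 29.52 CPM. Upk1b fell by 4.37, Csmd3, a synaptic adhesion gene, by 3.55, Tppp, a tubulin-binding protein gene, by 2.85, and Slc2a5 by 2.88. Of 32 mitosis genes, edgeR called 0, against 24 higher adjusted over the list alone (median log2 2.15, camera adjusted p = 4.3e-12, and 0.24 with an estimated correlation). Of 30 disease-associated genes, 6 rose and 24 were not called, and adjusted over the list alone 28 rose (median log2 2.30, camera adjusted p = 3.4e-21, and 0.14 with an estimated correlation). Of 22 phagocytic receptor genes edgeR called 0, against 12 higher adjusted over the list alone (median log2 1.18, camera adjusted p = 8.7e-08, and 0.2 with an estimated correlation). Mki67 lay 3.06 log2 units higher and was not called. Of 32 lysosome genes, 5 rose and 27 were not called, and adjusted over the list alone 27 rose (median log2 1.54, camera adjusted p = 5.8e-21, and 0.19 with an estimated correlation). Of 26 homeostatic genes, 1 fell and 25 were not called, and adjusted over the list alone 1 rose and 12 fell (median log2 -0.78, camera adjusted p = 0.00011, and 0.4 with an estimated correlation). Of 15 monocyte markers, 4 rose and 11 were not called, and adjusted over the list alone 14 rose (median log2 3.11, camera adjusted p = 5.4e-12, and 0.14 with an estimated correlation). They summed to 1507 CPM against 240.6 CPM in the female and 1376 CPM against 202.6 CPM in the male pair. Of 13 markers of border-associated macrophages, 1 rose and 12 were not called, and adjusted over the list alone 7 rose (median log2 2.68, camera adjusted p = 2.9e-05, and 0.28 with an estimated correlation). The count of calls ran from 0 without a day 1 or a day 7 pair to 720 without the day 4 male pair.

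At day 14 lipid and disease-associated genes were higher, beside higher monocyte and T cell markers. In edgeR, 17 genes were called, 13 higher and 4 lower. This direction turned in DESeq2 (1041 higher, 1107 lower), and the authors' table lists 1849 higher and 2030 lower, while the older dispersion estimate gave 508 higher and 501 lower. Clec7a rose by 5.53 (SE 0.57, adjusted p = 0.0388), from 10.73 to 598.1 CPM. Lpl rose by 4.92, and Thbs1 was called at 97.39 CPM against 2.547 CPM. Cd5l averaged 45.25 CPM at the wound against 0.2062 CPM, and Atp6v0d2, a proton pump subunit gene, 98.12 CPM against 0.2456 CPM. Ctse, the cathepsin E gene, averaged 34.64 CPM against 0.2401 CPM, Il1rn 23.11 CPM against 0.09004 CPM and Cd200r4, an activating receptor gene, 24.63 CPM against 0.07503 CPM. Upk1b fell by 3.87. Slc6a17, a vesicular transporter gene of neurons, was called at 0.771 CPM against 19.81 CPM, and Add2, an adducin gene, at 1.665 CPM against 34.18 CPM. Of 30 disease-associated genes, 4 rose and 26 were not called, and adjusted over the list alone 24 rose (median log2 2.93, camera adjusted p = 4.6e-22, and 0.23 with an estimated correlation). Of 20 lipid genes, 1 rose and 19 were not called, and adjusted over the list alone 14 rose (median log2 3.36, camera adjusted p = 1.6e-10, and 0.23 with an estimated correlation). Apoe lay 5.03 log2 units higher and was not called (adjusted p = 0.0827). Of 26 homeostatic genes, edgeR called 0, against 9 lower adjusted over the list alone (median log2 -0.70, camera adjusted p = 1.6e-10, and 0.37 with an estimated correlation). Of 15 monocyte markers, 1 rose and 14 were not called, and adjusted over the list alone 8 rose (median log2 2.41, camera adjusted p = 1.3e-07, and 0.23 with an estimated correlation). Of 13 T cell markers edgeR called 0, against 6 higher adjusted over the list alone (median log2 3.20, camera adjusted p = 5.4e-06, and 0.23 with an estimated correlation). Of 31 DNA replication genes it called 0, against 2 higher adjusted over the list alone (median log2 0.44, camera adjusted p = 0.019, and 0.61 with an estimated correlation). Of 73 ribosomal protein genes it called 0, and 0 adjusted over the list alone (median log2 0.69, camera adjusted p = 4.7e-09, and 0.58 with an estimated correlation). The count of calls ran from 0 without either day 1 pair, either day 14 pair or the day 7 female pair to 160 without the day 4 male pair.

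The next comparisons asked whether the effect of injury changed between successive days. No single gene passed the threshold, while several lists moved under the preset correlation. In edgeR, 0 genes were called from day 1 to 4, 4 to 7 or 7 to 14, with 1230, 358 and 3358 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.393, 1 and 0.421. DESeq2 called 55, 6 and 135, limma with voom weights 14, 0 and 0, and limma on log2 TPM 0 in each. From day 1 to 4 the injury effect on the homeostatic list rose by a median log2 of 1.27 (camera adjusted p = 1.1e-14, and 0.41 with an estimated correlation). For its 26 genes edgeR called 0, against 17 adjusted over the list alone. The list's pair median went from -1.78 to -1.33 in females and from -2.02 to -0.63 in males. P2ry12 in the non-injured libraries went from 3450 to 670.7 CPM in males and from 3435 to 5782 CPM in females. The male change thus rests partly on the day 4 non-injured library. The lysosome list gained 1.69 (camera adjusted p = 7.5e-17, and 0.41 with an estimated correlation), with 0 of 32 called against 20 adjusted over the list alone. From day 7 to 14 the ribosomal list lost ground (median log2 -0.89, camera adjusted p = 6.8e-15, and 0.82 with an estimated correlation), with 0 of 73 called, also adjusted over the list alone. The mitosis list did likewise (median log2 -1.84, camera adjusted p = 0.00098, and 0.82 with an estimated correlation), with 0 of 32 called, also adjusted over the list alone. The replication list also lost ground from day 7 to 14 (median log2 -1.16, camera adjusted p = 0.00094, and 0.82 with an estimated correlation), with 0 of 31 called, also adjusted over the list alone. Genes with the smallest p from day 1 to 4 included Hacd4, a fatty acid elongation gene (log2 5.68, adjusted p = 0.393), and Igf1 (log2 4.32, adjusted p = 0.592). From day 4 to 7 they included Ccl12, a monocyte attractant gene (log2 -2.58), and Arg1 (log2 -4.82), each at an adjusted p of 1. From day 7 to 14 they included Mcm5, a replicative helicase gene (log2 -3.98, adjusted p = 0.421).

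Calls were shared between days more often than independent draws from all tested genes would give, here named chance. The days come from a single fit that shares the dispersion of each gene. A count above chance therefore does not by itself show a shared response. Days 1 and 4 shared 91 higher genes where chance gives 2.05, and 54 lower genes where chance gives 0.865. Days 4 and 7 shared 84 higher genes (chance 1.38) and days 7 and 14 shared 11 (chance 0.0414). The shared counts were the same with a 2-fold threshold. Among the 2219 genes that rose on average, 452 had their highest fitted effect at day 1, 758 at day 4, 662 at day 7 and 347 at day 14. Among the 2277 that fell, 811 were lowest at day 1, 339 at day 4, 561 at day 7 and 566 at day 14. These counts rank fitted effects from 2 pairs per day. Since 0 genes were called for a change between successive days, they do not show a time course.

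The comparison of the sexes asked whether males and females respond differently. Spp1 was higher and Upk1b lower at the wound in 8 of 8 pairs. Across 9025 genes, which are not independent replicates, female and male injury effects correlated with an r of 0.832 at day 1, 0.603 at day 4, 0.665 at day 7 and 0.322 at day 14. In the 4 female pairs edgeR called 1410 genes, 932 higher and 478 lower, and in the 4 male pairs 2014, 519 higher and 1495 lower. The female direction turned in median-ratio scaling (48.8% higher against 66.1%), in DESeq2 (1571 higher, 2094 lower) and in limma on log2 TPM (181 higher, 615 lower), so the balance of rises and falls is no stable difference between the sexes. In females Spp1 rose by 8.68 (SE 0.61, adjusted p = 0.00146) and Gpnmb by 8.25. Apoc2 averaged 100 CPM against 0.2567 CPM and Igkc 33.22 CPM (11.24 without the day 7 pair) against 0.01024 CPM. Gpr165 averaged 1.079 CPM against 31.93 CPM (0.1022 against 5.419 without the day 4 pair). Upk1b fell by 4.79, Meg3, a neuronal non-coding RNA, by 4.45, and Slc22a8, an organic anion transporter gene of vessels, by 4.26. In males Spp1 rose by 6.64 (SE 0.64, adjusted p = 0.00122), Cxcl2, a neutrophil attractant gene, by 6.20, and Cd5l by 6.03, while Lamp5 fell by 5.51. Gdf3 was called at 33.26 CPM at the wound against 0.478 CPM (14.63 against 0.04586 without the day 7 pair). Tmem198, a membrane protein gene, was called at 0.6262 CPM against 25.02 CPM, Kcnj9, a potassium channel gene, at 0.7864 CPM against 29.78 CPM, and Apc2, a microtubule gene of neurons, at 1.896 CPM against 36.35 CPM. Without the day 4 pair their non-injured means were 7.814, 17.04 and 11.24 CPM. The female count fell to 126 without the day 1 pair, 6 without the day 4 pair and 15 without the day 7 pair, and reached 2957 without the day 14 pair. The male count fell to 138 without the day 4 pair, 849 without the day 7 pair and 398 without the day 14 pair.

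For the difference between the sexes in the mean injury effect, edgeR called 0 genes, with 2094 at an unadjusted p under 0.05, against 152 in DESeq2, 12 with voom weights and 0 on log2 TPM. Among the genes with the smallest p, Ncan, a brain proteoglycan gene, had a female minus male effect of 3.25 (SE 0.39, adjusted p = 0.0715). Ndrg2, an astrocyte gene, had 3.02 and Gja1, the connexin 43 gene, 2.45 (adjusted p = 0.147). The astrocyte list had a female minus male difference of 2.25 in its medians (exact two-sided permutation p = 0.0571, adjusted p = 0.528). Astrocyte markers on the non-injured side summed to 8362 CPM in the day 4 and 5083 CPM in the day 7 male library, while at day 1 they summed to 846.2 CPM in the male and 848.3 CPM in the female one. Hspa1a, a heat shock gene, went the other way (log2 -2.88, adjusted p = 0.101). An exact two-sided permutation test of 4 against 4 pairs can give no p under 0.0286, so with 37 lists it could not call a single list that differs between the sexes. The neutrophil list reached that minimum (adjusted 0.528), with medians of -0.03 to 0.49 in female and 0.84 to 2.42 in male pairs. Within 1 sex and day there was 1 pair and no test. Astrocyte list medians were -1.94 in the female and -1.92 in the male pair of day 1, -0.44 and -3.43 at day 4, 0.54 and -2.06 at day 7, and 1.33 and -2.09 at day 14. Homeostatic genes were lower in both day 14 pairs, with list medians of -1.02 in the female and -0.61 in the male pair.

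**Figure D3:**
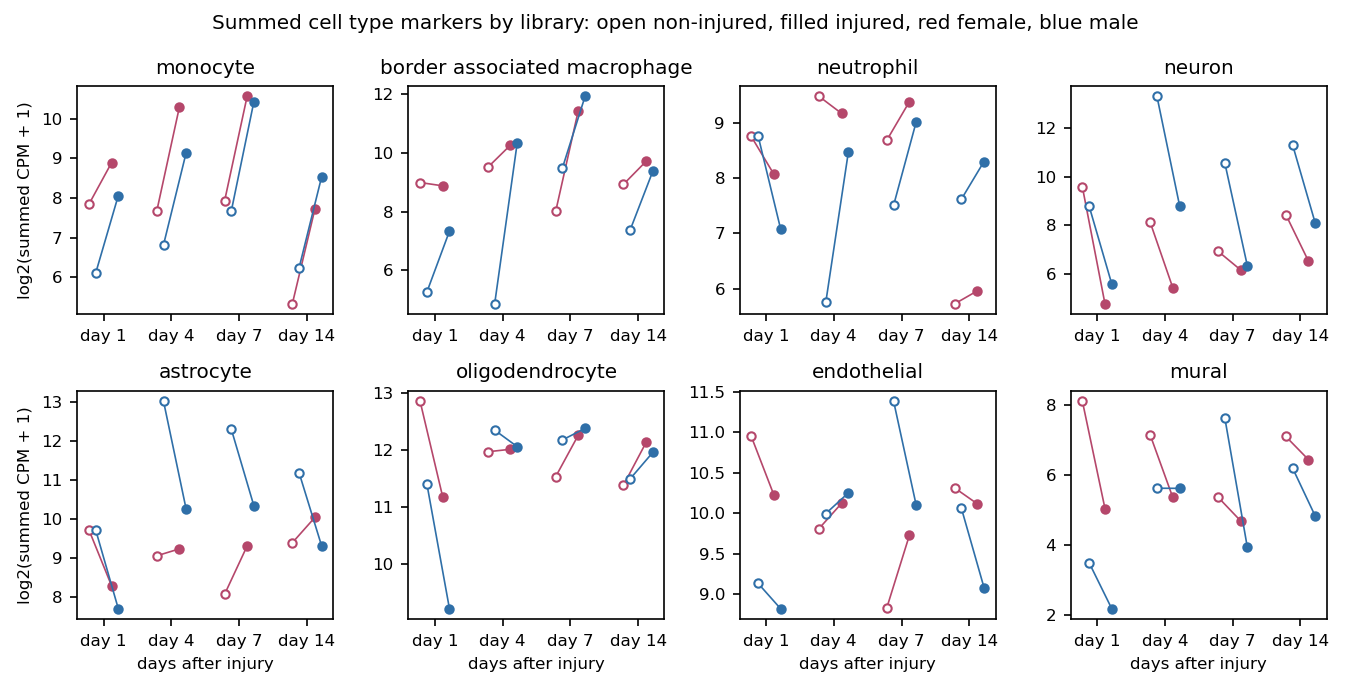
Each panel shows log2 of the summed CPM, plus 1, of the markers of a cell type (vertical axis) by day after injury (horizontal axis). Open points are non-injured and filled points injured libraries, red for females and blue for males, and lines join the 8 pairs. Neuron markers were lower at the wound in 8 of 8 pairs and monocyte markers higher in 8 of 8.

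The non-injured hemisphere was compared between days and sexes, as the background against which injury is read. Between days edgeR called 0 genes, with 459 at an unadjusted p under 0.05 and a smallest adjusted p of 0.104 for Actc1, a muscle actin gene, while DESeq2 called 10. Mb, the myoglobin gene, came next (adjusted p = 0.322). Both rest on the day 4 male library, with 206.2 CPM of Actc1 and 95.06 CPM of Mb, against at most 0.1127 and 0.2048 CPM in the other 7. Leaving out the day 7 female library raised the count to 47. Between females and males edgeR called 7 genes, against 1193 in DESeq2. Xist and Tsix, its antisense partner, were higher in females, and Ddx3y, Eif2s3y, Uty and Kdm5d, all Y-linked, were higher in males. Acta2, the smooth muscle actin gene, was higher in females (log2 5.58, SE 0.93, adjusted p = 0.0169). It was not called once the genes that define the sex label were left out of the fit. The protocol does not keep the strand, so counts of Xist and Tsix are not fully separable. The count became 0 without the day 1 female or the day 14 female library, 1 without the day 14 male library, 12 without the day 1 male library and 18 without the day 7 female library.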

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

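The tests of neuron against oligodendrocyte markers, of the neuron markers without 1 pair, of their correlation within sides, of transcript length, and of ribosomal genes relative to the median gene were chosen after their results had been seen.

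Of 42 groups of 8 libraries examined by Dixon's gap test, 8 held a library far from the others. Chance gives about 1 in 20 groups where values are normally distributed. The values were not put on a log scale, and neuron markers ran from 121.6 to 10010 CPM on the non-injured side, so that rate need not hold here. The day 4 male non-injured library had 25.7% mitochondrial counts, 10010 CPM of neuron markers and 226.7 CPM of oligodendrocyte precursor markers, each the highest on its side. The day 4 male injured library had 227.4 CPM of oligodendrocyte precursor markers, also the highest on its side. The day 7 male libraries had 30.71 CPM of T cell markers on the non-injured and 127 CPM of fibroblast markers on the injured side. That non-injured library also held the most Spp1 (1987 CPM), Gpnmb (354.1 CPM), Msr1 (162.8 CPM) and Cd74 (1349 CPM) of its side, all genes raised at the wound. For Lpl and Hmox1 another non-injured library was highest, and none of these genes entered the gap test. The day 1 female non-injured library had 70.35 CPM of erythroid markers, and the day 4 female injured library 219 CPM of Cx3cr1. Without the day 4 male pair the mean injury effect called 3699 genes against 4496.

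Between successive days, the 2 pairs of 1 day lay on opposite sides of 0 from the 2 pairs of the next for 5 lists, and this difference between pair medians was not tested. The later minus the earlier day was 1.26 for MHC class II genes and 1.46 for phagocytic receptors from day 1 to 4. It was -1.20 for cholesterol biosynthesis from day 1 to 4, -2.04 for erythroid markers from day 4 to 7 and 0.86 for oligodendrocyte precursor markers from day 7 to 14. In the gene-level model, camera gave adjusted p-values for these changes of 1.2e-07, 6.5e-06, 0.0087, 0.53 and 0.88, and with an estimated correlation of 0.41, 0.41, 0.57, 0.9 and 1.

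Neuron markers were lower at the wound in every pair. A carry-over of neurons and oligodendrocytes alike is argued against. The neuron list fell further than the oligodendrocyte list by a mean log2 of -2.77 (SD 1.63, 8 of 8 pairs below 0, exact two-sided sign-flip p = 0.00781). The endothelial, astrocyte and mural list medians averaged -1.62, -1.25 and -1.23, and a carry-over of these cells together with neurons was not tested. For the neuron list a single unusual library is argued against too, since the other 7 pairs average -2.48 (SD 0.82, 7 of 7 below 0) against -4.41 in the day 4 male pair. With the mean of each side taken off, the 14 markers varied together over the 16 libraries (median pairwise rho 0.75, percentile 100 among 1000 lists matched on expression, whose median rho was 0.0882). Markers of 1 cell type vary together wherever its RNA content differs between libraries, so this cannot decide how neuronal RNA entered them. Whether it came from debris, attached fragments or RNA taken up by microglia was not tested, and a biological fall at the wound, where neurons are lost, stays open.

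Homeostatic genes were lower and monocyte markers higher at the wound. An equal dilution of microglial RNA by cells that lack these genes is argued against: the 26 members ranked alike in females and males (rho 0.907 across genes, permutation p = 1e-05, the smallest 1e+05 permutations can give) and ranged from -2.94 to 0.75. Blood-derived cells within the sorted gate may still contribute. Across pairs the monocyte and homeostatic medians gave r = 0.171 (exact p = 0.679) and rho = 0.0476 (exact p = 0.935), and r = -0.223 without the 2 farthest pairs, so 8 pairs leave this open. A change of state within microglia, which the design names as injury, stays open beside it and was not separately tested.

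Ribosomal protein genes were higher at the wound. Scaling between libraries is argued against, because the list stayed above the median gene by a mean log2 of 1.06 (SD 0.47, 8 of 8 pairs). Short transcripts may account for part of the rise. Of 1000 lists matched on transcript length (median 766 against 751 bases) and expression, 0% reached the list's median of 1.26 (matched median 0.80, highest 1.03). The matched genes were drawn independently, while ribosomal genes may vary together, so this cannot decide whether length accounts for all of it. The number of genes detected may play a part, since across 8 pairs it gave r = -0.573 (exact p = 0.122, adjusted 0.244) and rho = -0.548 (exact p = 0.171, adjusted 0.342), and r = -0.489 without the 2 farthest pairs, which leaves it open. A biological rise in translation capacity also stays open.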

How the results depend on the processing

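The fits of 32 separate columns, without pairs, with the older dispersion estimate, with stricter filters, with voom, without 3 male pairs and with 1 effect for all days were chosen after the data had been seen. Counts of called genes are given for days 1, 4, 7 and 14 in that order, then for the mean over days.

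Scaling and test. The cause of the differences was not tested. Against 301, 584, 107, 17 and 4496 genes, median-ratio factors gave 538, 626, 91, 40 and 4763, DESeq2 2481, 1899, 2188, 2148 and 6518, limma on log2(TPM + 1) 565, 319, 179, 115 and 4371, voom 770, 1108, 845, 139 and 4696, and the older dispersion estimate 1487, 1344, 1320, 1009 and 4714. A 2-fold threshold left the single days unchanged and gave 3609 on average. One injury effect for all days gave 5260 on average.

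Filters and samples. Without a filter the counts were 101, 210, 16, 2 and 3499, with CPM above 1 in at least 8 libraries 1234, 1150, 601, 268 and 4987, and at a mean CPM of at least 10 they were 997, 622, 167, 87 and 3315. Without the pair term they were 12, 19, 0, 7 and 2097, without the day 4, 7 and 14 male pairs 2350, 736, 1213, 178 and 4398, and with only the compared libraries 1576, 0, 0 and 90. Leave-one-out fits of the 8 pairs gave 0 to 845, 0 to 764, 0 to 720, 0 to 160 and 1758 to 4992. Where a day kept 1 pair, that pair was assumed to vary like the others.

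Pairing by replicate number. The 32 columns as separate samples gave 14735, 15221, 15966, 12005 and 12167, and the replicate block 14404, 14775, 15656, 11839 and 12063. By construction these fits take the difference between columns for the spread. For the changes between days the block gave 11030, 10662 and 10488 and the separate columns 11387, 11162 and 10675. For the sex difference they gave 10131 and 10275, for female pairs 12401 and 12524, and for male pairs 14476 and 14728. The separate columns gave 19766 between days and 14656 between sexes on the non-injured side. The block took the called lists from day 4 to 7 from 8 to 12, and the lower ones among them from 2 to 6.

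Changes of the injury effect between days had 0 calls. DESeq2 gave 55, 6 and 135, the older estimate 119, 15 and 54, and voom 14, 0 and 0. Leave-one-out fits gave 0 to 1, 0 and 0. The sex difference had 0 calls, against 152 in DESeq2, 87 with the older estimate and 12 with voom, and apart from the block and the separate columns the other alternatives gave 0.

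Female pairs, with 1410 calls, gave 3665 in DESeq2, 695 without a filter, 796 on log2 TPM, 2606 with the older estimate, 2687 with CPM above 1 in 8 libraries and 6 to 2957 in leave-one-out fits. Male pairs, with 2014, gave 4214 in DESeq2, 800 on log2 TPM and 138 to 1666 in leave-one-out fits. Between days on the non-injured side, the count of 0 became 10 in DESeq2, 26 without a filter, 25 with the older estimate and 0 to 47 in leave-one-out fits. Between sexes there, the count of 7 became 1193 in DESeq2, 270 without a filter, 1 on log2 TPM, 193 with the older estimate, 0 at a mean CPM of at least 10, 110 with voom and 0 to 18 in leave-one-out fits.

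With an estimated correlation, camera called 0 lists in every comparison, against 23, 27, 26 and 22 by day, 20, 8 and 14 for the changes and 26 on average. The sum of calls shared between days did not change with a 2-fold threshold.

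Of 3603 values of single named genes under alternatives, 2917 kept direction and call, 589 were no longer called, 91 became called and 6 changed sign. Trem2 on average, not called, became -0.08 on log2(TPM + 1). Actc1 between days became -16.97 in DESeq2, -9.99 without the day 1 male and -4.08 without the day 4 male library (leave-one-out range to 14.16), and Mb -8.89 and -4.47 without the same libraries (range to 12.74). These are the widest of 3 differences between days, so their sign depends on which day is widest.

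Planned tests within 1 sex and day, and of the sex difference at a single day, were not run because the summed libraries leave no residual degrees of freedom.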

Other observations

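The comparison with the deposited tables, and leaving out the genes that define the sex label, were chosen after the values had been seen, and the exchanges of samples between groups were planned.

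The authors' own comparison tables, made with DESeq2 per the submitters' processing notes, list 3408, 3702, 4656 and 3879 genes at an adjusted p under 0.05 for days 1, 4, 7 and 14 with both sexes together. Their tables within 1 sex list 13268, 12460, 13512 and 11546 genes in females and 12169, 12384, 13152 and 12979 in males, which are tests between columns that differ by little more than counting noise. Of the genes called here, 296 of 301 at day 1, 566 of 584 at day 4, 107 of 107 at day 7 and 17 of 17 at day 14 are also called in the tables with both sexes, all in the same direction.

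Exchanging the sides within pairs tested whether chance can give as many calls. Of 60 exchanges drawn from 128, only 1, the real one, gave as many as 4496 genes, and the highest other gave 1610. This argues against chance for the mean over days. It does not exclude chance, because only 60 exchanges were drawn and that mean was chosen after the values had been seen. For the 4 female pairs there are only 8 exchanges, too few for a share under 0.05, with 1410 genes in the real one and 0 in the highest other. For the 4 male pairs there are also 8, again too few, with 2014 in the real one and 0 in the highest other. For the sex difference in the injury effect the real count is 0, so 32 of 32 splits had to give as many (highest other 0), and this decides nothing about chance. For females against males on the non-injured side, 6 of the 7 called genes define the sex label. With Xist, Tsix and the Y-linked genes left out (170 genes), Acta2 is no longer called and the real count is 0. For that reason 32 of 32 splits had to give as many (highest other 0), and this decides nothing about chance.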
